A study of Arabidopsis thaliana with 2 samples.

How the data were processed

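Polyadenylated RNA of leaves was sequenced from wild-type Col-0 and from WRKY75 RNAi plants, each 28 days old, with 1 library per genotype, per the labels. Alignment used Bowtie and the TAIR10 build, per the submitters' processing notes, and its version, the read counter, the strand setting and any filter on reads are not given in the sources used here. The authors deposited, per the file headers, read counts per transcript model, RPKM values, the log2 ratio of RPKM in WRKY75 RNAi over wild type, a p-value and a false discovery rate, in 1 table of 998 lower and 1 of 1360 higher transcript models, and an unnamed table of 93 ontology terms with their p-values for the lower genes. The name of the authors' test is not given. No numeric column of the gene tables was left unmapped.

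What the values hold was checked from the values themselves. Reads divided by the product of the deposited RPKM and length gave a median total over rows of 41328980 for wild type and 38042482 for WRKY75 RNAi. The deposited RPKM values are taken as scaled to these totals, and no further normalisation was found. The deposited log2 ratios equal those recomputed from the RPKM values to within 7.3e-08 where both libraries had reads, and elsewhere an RPKM of 0 was replaced by 0.001. In the text, ratios are recomputed from RPKM. For loci at 0 reads only reads, or a ratio against a floor of 3 reads per library with the limit of its interval, are given. The ratio against the floor leaves out counting error in the other library. The smallest deposited absolute log2 ratio was 1.00 and the largest deposited p-value 0.0102. Among 955 intron-rich transcript models, the deposited length was a median of 0.961 of the genomic span and 1.48 times the spliced length in the TAIR10.1 annotation. RPKM values of intron-rich genes are therefore low compared with those of other genes, while ratios between the libraries are not affected.

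The relation of deposited p-value, false discovery rate and rank gave 31475 tested transcript models as the number at which ranks were whole (mean distance from a whole number 0.00029, against 0.056 at the next best number, over 416 rows). By the same ranks 11639 of these models, 37.0%, had a deposited p-value at or below 0.0102, of which 2358 are in the tables. These ranks carry any fault in the deposited p-values. Deposited p-values were compared with 2 times the tail of a conditional negative binomial distribution of the reads of 1 library given those of the other. All 998 rows of lower genes lay within 0.5% of it, but only 528 of 1360 rows of higher genes (a row counts as within it where both values are too small to be stored), so the deposited p-values are not used to rank genes.

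Transcript models were reduced to 1 per locus, the model with the most reads (170 loci had several). The row with no gene identifier was left out; it held 0.103% of the wild-type and 0.0384% of the RNAi total. Of 2159 loci, 2147 were found in the TAIR10.1 gene table, which served for symbols, descriptions, overlaps and families. Since the builds are not named alike no coordinates are printed; the chromosome is the digit in the locus identifier, or C for the chloroplast. Transcripts of genes named by the rule, and of groups chosen afterwards, were compared with all other transcripts by BLAST 2.17.0. An alignment of at least 50 bases with at least 97% identity over its whole length was counted as shared. Among genes named by the rule, only AT5G28700 had such an alignment with a gene that does not overlap it, over 4.16% of its transcript. Shorter stretches of high identity within less similar copies were not searched for, and other named genes, such as PDF1.2B, were not compared. Reads shared between related genes are therefore not excluded.

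No test of genotype was made, because 1 library per genotype gives no spread between plants. Fixed beforehand were 18 gene lists, 15 families defined by words in gene descriptions, the rule for named genes and the other settings that were to be tried, all before the data were examined. For lists with at least 5 listed members, the median deposited log2 ratio was placed among 10000 random lists of the same size from the listed genes, matched on mean RPKM in 5 bins, as a description of these libraries. Every listed gene lies beyond a 2-fold difference, so such a median can be near the centre of random lists although all members point one way. The genes named are WRKY75; the 8 lower and 8 higher genes with the largest ratios among those with reads in both libraries and a higher value at or above the median of listed genes; up to 4 members of each list with the largest ratios; the 3 most abundant genes per direction; and 2 genes per direction at 0 reads in 1 library. Other members named beside a list were chosen after their values were seen. In simulated libraries of the same depth, with 2159 loci and counting error alone, 77.0% of changes of 1.5 and 91.0% of changes of 2 on the log2 scale passed thresholds of 2-fold and p of 0.01, as did 0.306% of unchanged loci, and 95.7% of intervals held the true ratio. The simulated reads were independent, whereas low read counts in these libraries were mostly even. These rates therefore check the calculation and do not describe error in the libraries themselves. Lists drawn without a shift had a median percentile of 48.3 (40 lists), and a list shifted downwards lay at 0.

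Alternatives were a stricter ratio, a stricter false discovery rate, a filter on low values, counting every row, pseudocounts of 0.1 and 5 RPKM and unmatched random lists. Chosen after seeing the data were recomputed p-values, halved reads and the exact test of edgeR 4.0.16 in R 4.3.3 with an assumed biological coefficient of variation of 0.2 or 0.4. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.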

Results

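Messenger RNA abundance was measured by sequencing polyadenylated RNA from rosette leaves of 28-day-old *Arabidopsis thaliana* plants. There were 2 libraries, 1 from the wild-type accession Col-0 and 1 from plants in which the transcription factor gene WRKY75 was targeted by RNA interference (RNAi, silencing by a double-stranded RNA transgene). The library totals that underlie the deposited values were 41328980 reads for the wild type and 38042482 reads for the RNAi plants. The tables analysed here hold only transcripts that the authors selected for a difference: 931 loci listed as lower and 1231 listed as higher in WRKY75 RNAi, 2159 loci in all, of which 3 were in both tables through different transcript models. All 2358 rows took 6.80% of the wild-type total and 7.67% of the RNAi total. These shares include every listed model of a locus and the row with no gene identifier, so some reads may be counted more than once. With 1 library per genotype no difference has a replicate check. The intervals given below are exact (Clopper-Pearson) 95% intervals of the ratio of reads and cover counting error only, and a gene absent from the tables is called not listed, which does not mean that it was equal in both libraries.

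The targeted gene was the lower of the pair in the RNAi library. WRKY75 (AT5G13080), which encodes a WRKY-domain transcription factor, had 29.2 RPKM (reads scaled to the deposited gene length and library size) from 1699 reads in wild type. In WRKY75 RNAi it had 8.87 RPKM from 476 reads, or 30.4% of the wild-type value. Its log2 ratio was -1.72 (interval -1.87 to -1.57). The direction is the one the labels call for. Of the 6 closest WRKY relatives examined (WRKY45, WRKY43, WRKY24, WRKY56, WRKY13 and WRKY12), 0 were listed. Whether reads of the RNAi transgene itself are part of the WRKY75 count is not given in the sources used here.

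The series title places WRKY75 beside salicylic acid and reactive oxygen species in leaf senescence, so the comparison asks which leaf transcripts of these processes differ when WRKY75 is reduced. Genes of salicylic acid response were listed in 1 direction only: 11 of 29 as lower and 0 as higher. PR1 (AT2G14610), the standard marker of salicylic acid signalling, was at 1420 RPKM in wild type and 151.7 RPKM in WRKY75 RNAi, 10.7% of wild type (log2 ratio -3.23, interval -3.27 to -3.18). NIMIN1 (AT1G02450), an interactor of the salicylic acid receptor NPR1, was at 30.8% of wild type on only 60 and 17 reads (log2 ratio -1.70, interval -2.57 to -0.90). The plant natriuretic peptide gene PNP-A (AT2G18660) was at 36.0% and AIG1 (AT1G33960) at 39.0% of wild type. The listed members' median log2 ratio of -1.18 lay at the 22.3 percentile of 10000 random lists of equal size drawn from the listed genes and matched on abundance (13.7 when unmatched), so the size of their median was not extreme among listed genes.

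Salicylic acid synthesis and metabolism was split, with 9 of 25 members listed as lower and 6 as higher. On the lower side stood the transcription factor genes CBP60G (AT5G26920; 75.1 RPKM in wild type and 21.4 RPKM in WRKY75 RNAi, log2 ratio -1.81, interval -1.88 to -1.75), SARD1 (-1.35) and WRKY46 (-1.53), the isochorismate synthase gene ICS1 (AT1G74710; -1.45), PBS3 (-1.54), which acts on isochorismate, the immune regulators PAD4 (-1.52) and NDR1 (-1.23), and the genes ALD1 (-1.22) and FMO1 (-1.23) of pipecolic acid metabolism. The higher members were BSMT1 (AT3G11480), a methyltransferase that makes methyl salicylate, ICS2 (AT1G18870), EPS1 (AT5G67160), the phenylalanine ammonia-lyase genes PAL1 (1.02) and PAL4 (1.35), and the salicylic acid glucosyltransferase gene UGT74F2 (1.07). BSMT1 rested on 50 and 1048 reads (log2 ratio 4.51, interval 4.099 to 4.949), ICS2 on 15 and 116 reads (3.07, interval 2.29 to 3.95, or 2.199 with a pseudocount of 0.1 RPKM) and EPS1 on 168 and 474 reads (1.62, interval 1.36 to 1.88). The median of the 15 listed members was -1.23, at the 10.35 percentile of random lists (6.645 when unmatched).

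**Figure D1:**
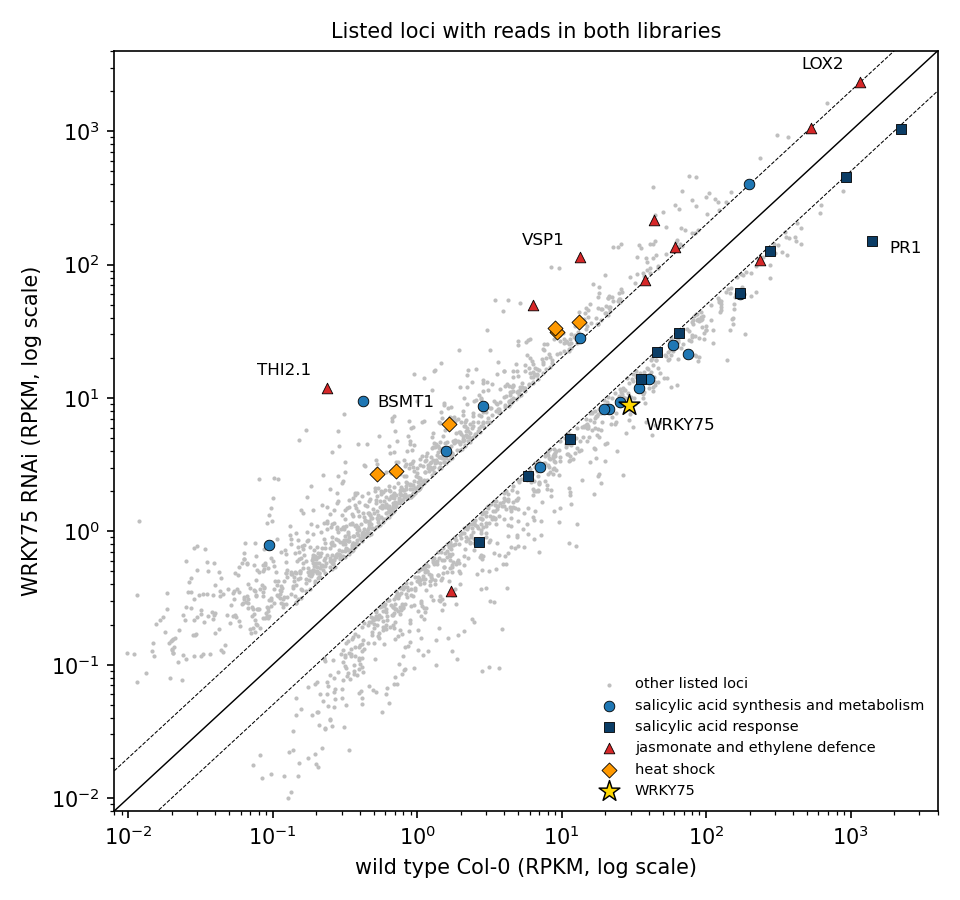
Abundance of each listed locus with reads in both libraries, wild type Col-0 on the horizontal and WRKY75 RNAi on the vertical axis, both in RPKM on log scales, with 1 point per locus. The solid line marks equal values and the dashed lines 2-fold differences; coloured symbols are the listed members of 4 gene lists, the star is WRKY75 (29.2 and 8.87 RPKM), PR1 lies below the lines and THI2.1, VSP1 and LOX2 above them, and the empty band is the authors' selection.

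In the list of pattern-triggered immunity and camalexin, 6 of 14 members were likewise listed only as lower, and 8 were not listed. All 6 are named here, and their count does not speak for the camalexin pathway as a whole. CYP81F2 (AT5G57220), a cytochrome P450 of indole glucosinolate metabolism, was at 14.8% of wild type (18.23 and 2.698 RPKM; log2 ratio -2.76, interval -2.97 to -2.55). MYB51 (AT1G18570), a regulator of the same pathway, was at 22.8%, the transcription factor gene WRKY33 (AT2G38470) at 35.5% and the flagellin-induced kinase gene FRK1 (AT2G19190) at 44.0%, while the flagellin receptor gene FLS2 had a log2 ratio of -1.11 and CYP82C2 one of -1.15. Their median was -1.34, at the 9.32 percentile. Among families found by annotation words, 14 WRKY genes were listed as lower, WRKY75 included, and 1 as higher (WRKY67, on 0 and 7 reads), with a median at the 0.465 percentile. Resistance proteins of the TIR-NBS-LRR and NB-ARC classes numbered 21 lower and 0 higher (median -1.25, 3.02 percentile), cysteine-rich receptor-like kinases 11 lower and 1 higher (median -1.27, 6.19 percentile), and lectins 19 lower and 8 higher (median -1.28, 1.67 percentile, or 1.09 when unmatched), a count that leaves out the higher genes MBP1, MBP2 and JAL30, for which the descriptions searched lack the word lectin. The lectin family was mixed, so its median does not describe every class in it. Of its members with a JAL name, JAL23 (log2 ratio 2.425), JAL34 (1.696) and JAL33 (1.266) were higher and JAL22 (-2.465) was lower. According to the authors' deposited table of ontology terms for the lower genes, defense response held 69 of 857 list genes against 637 of 27594 background genes (adjusted p 2.46e-16) and response to chitin 24 against 104 (adjusted p 3.64e-12).

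Senescence and reactive oxygen are the other processes named in the series title. Of 28 genes of leaf senescence and chlorophyll breakdown, 4 were listed as lower and 1 as higher. WRKY53 (AT4G23810), a transcription factor gene of early senescence, was at 203.5 RPKM in wild type and 57.9 RPKM in WRKY75 RNAi (log2 ratio -1.81, interval -1.87 to -1.76). The senescence regulator gene NAP (AT1G69490) was at 29.5% of wild type (-1.76, interval -2.10 to -1.44), SAG21 (AT4G02380) at 31.5% and WRKY6 (AT1G62300) at 44.9%. The phosphatase gene SAG113, also named HAI1 and so a member of the abscisic acid list as well, was the higher member (1.16). The median of these 5 was -1.67, at the 2.38 percentile (4.77 when unmatched). SAG12, SAG13 and the chlorophyll catabolic genes SGR1, PPH, PAO and NYC1 were not listed. Of 22 genes of reactive oxygen production and scavenging, BAP1 (AT3G61190) was listed as lower (178.9 and 83.1 RPKM, log2 ratio -1.11). The peroxidase gene APX2 (AT3G09640) was listed as higher, on 0 and 10 reads. This is 3.62-fold against a floor of 3 reads per library, and the lower limit of the interval of its log2 ratio was 1.284. The catalase genes CAT1, CAT2 and CAT3 and the oxidase genes RBOHD and RBOHF were not listed. The family found by the words peroxidase superfamily or a PRX or PER name, which leaves out ascorbate peroxidases such as APX2, numbered 9 lower and 0 higher (median -2.24, 0.05 percentile), among them Prx37 (-2.24) and the dioxygenase gene DOX1 (-3.46).

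The listed jasmonate genes were mostly higher. Of 23 genes of jasmonate and ethylene defence, 8 were higher and 2 lower. The thionin gene THI2.1 (AT1G72260) had 10 reads in wild type and 460 in WRKY75 RNAi (0.2393 and 11.96 RPKM; log2 ratio 5.64, interval 4.75 to 6.71). The vegetative storage protein genes VSP1 (AT5G24780; 3.08, interval 2.97 to 3.19) and VSP2 (AT5G24770; 2.96, interval 2.81 to 3.10) and CORI3 (AT4G23600; 2.31, interval 2.27 to 2.36) followed. The jasmonate biosynthesis genes LOX2 (1162 and 2359 RPKM) and AOC1 (529.9 and 1064 RPKM) were 2.03-fold and 2.01-fold higher, and the repressor genes JAZ8 and JAZ10 had log2 ratios of 1.14 and 1.02. The lower members belong to the branch shared with ethylene, namely the transcription factor gene ERF1 (-2.27, on 68 and 13 reads) and the defensin gene PDF1.2B (-1.13). The median of the 10 was 1.08, at the 76.3 percentile of random lists matched on abundance but at the 50.5 percentile of unmatched lists, so it was not extreme among listed genes.

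**Figure D2:**
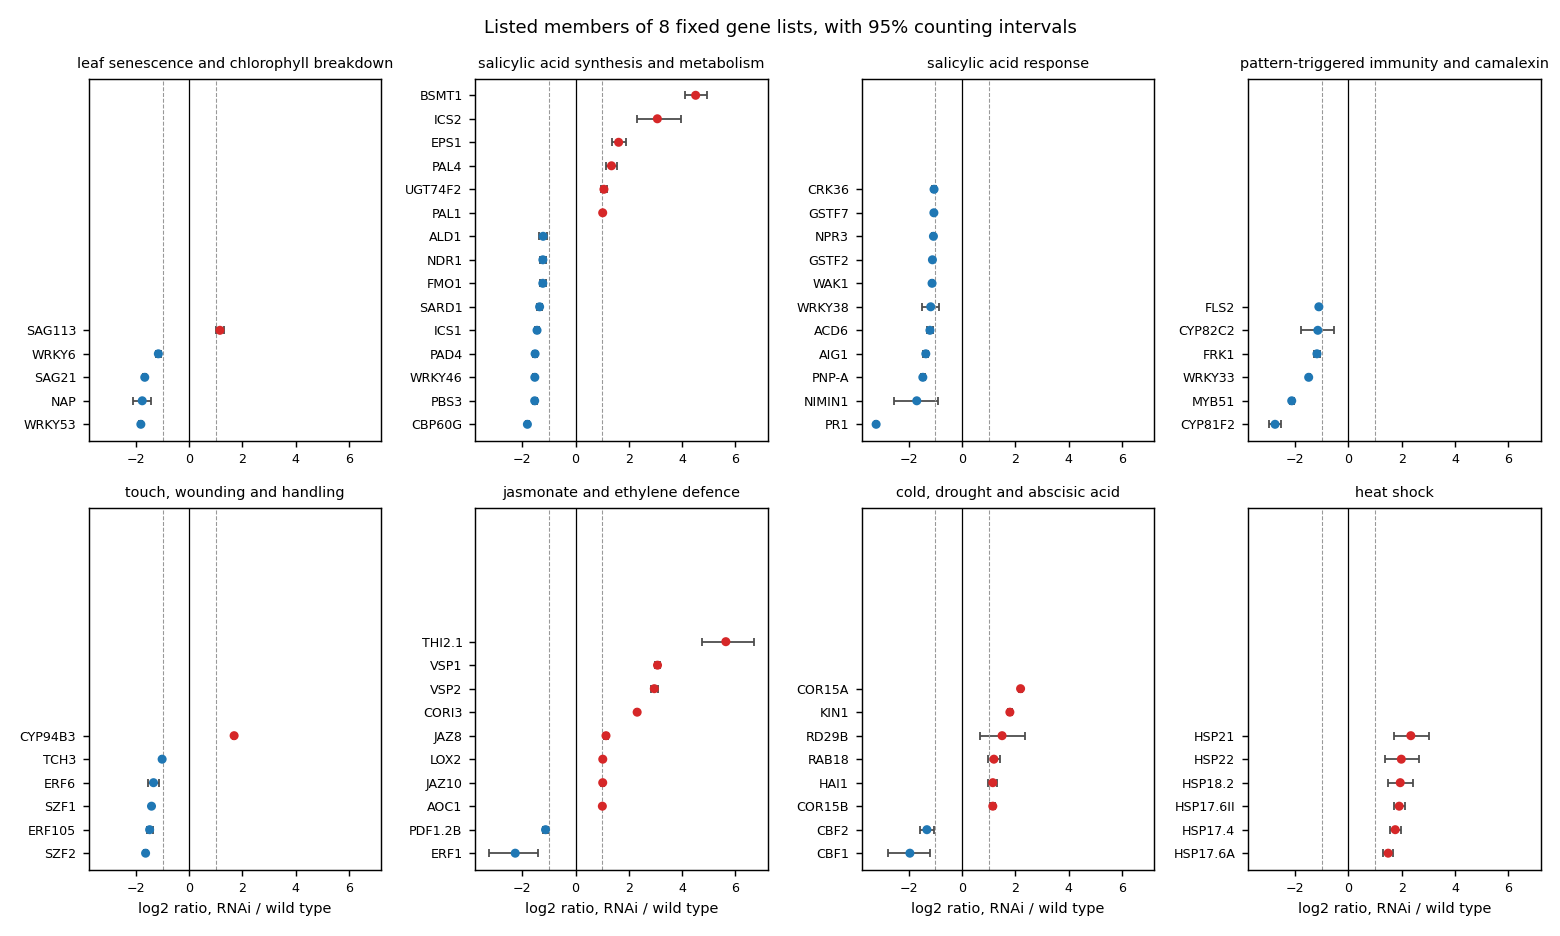
Log2 ratio of WRKY75 RNAi over wild type for each listed member of the 8 gene lists that have at least 5 listed members, 1 point per gene, blue where lower and red where higher, with bars for exact 95% intervals of the read ratio. Dashed lines mark the authors' selection at 1 and -1; the 11 salicylic acid response genes and 6 immunity genes all lie on the left and the 6 heat shock genes on the right.

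Stress lists pointed in different directions. In the list of heat shock genes, 6 of 11 members were listed as higher and 0 as lower, with a median of 1.93 at the 99.4 percentile. All 6 encode small heat shock proteins, chaperones of heat-damaged proteins. HSP21 (AT4G27670) had 24 and 112 reads (log2 ratio 2.34, interval 1.70 to 3.04), HSP22 (AT4G10250) a ratio of 1.99, HSP18.2 (AT5G59720) of 1.94 and HSP17.6II (AT5G12020) of 1.91, while HSP101 (AT1G74310), the HSP70 gene AT3G12580 and HSFA2 (AT2G26150) were not listed. The wider family of heat shock proteins by annotation, which takes in these 6, numbered 15 higher and 0 lower (99.96 percentile), among them the HSP70 genes AT1G16030 (1.301) and AT2G32120 (1.58). In the list of cold, drought and abscisic acid, 6 of 15 were higher and 2 lower. COR15A (AT2G42540; 60.8 and 279.4 RPKM, log2 ratio 2.199, interval 2.138 to 2.261), KIN1 (AT5G15960; 1.80) and RD29B (AT5G52300; 1.504, on 18 and 47 reads) were higher, whereas CBF1 (AT4G25490; -1.96, on 76 and 18 reads) and CBF2 (-1.32), which encode cold-induced activators of COR15A and KIN1, were lower. The median was 1.18, at the 74.3 percentile.

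Of 14 genes that respond within minutes to touch, wounding and handling, 5 were listed as lower and 1 as higher (median -1.38, 8.74 percentile). SZF2 (AT2G40140) was at 32.2%, ERF105 (AT5G51190) at 35.8% and SZF1 (AT3G55980) at 37.5% of wild type, and CYP94B3 (AT3G48520), an enzyme of jasmonate catabolism, was 3.22-fold higher. Of 15 phosphate starvation genes, RNS1 (AT2G02990), a ribonuclease gene, was 11.4-fold higher (8.46 and 96.1 RPKM, log2 ratio 3.51, interval 3.37 to 3.65), and MGD3 (AT2G11810) was listed as higher on 6 and 24 reads (2.12, interval 0.79 to 3.70), but with a pseudocount of 0.1 RPKM its ratio is 0.999, within 2-fold. Of 9 flowering time genes, the repressor genes MAF5 (AT5G65080; -2.06, on 227 and 50 reads) and FLC (AT5G10140; -2.05, on 18 and 4 reads, interval -4.07 to -0.45) were listed as lower; with a pseudocount of 0.1 RPKM FLC is at -0.56, within 2-fold.

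The largest differences among loci with reads in both libraries, at or above the median listed abundance of 1.95 RPKM, included genes of other functions. Lower were AT5G57760 (84 and 2 reads, log2 ratio -5.27, interval -8.34 to -3.38), AT4G28460 (71 and 2 reads, -5.03), the MIZU-KUSSEI-like gene AT4G39610 (137 and 4 reads, -4.98), AT2G30615 (-4.39), the cation exchanger gene CHX17 (AT4G23700; 1868 and 107 reads, -4.01, interval -4.30 to -3.73), AT2G44240 (-3.78), the receptor-like protein gene RLP11 (AT1G71390; -3.55) and AT1G47395 (38 and 3 reads, -3.54). Higher, besides THI2.1 and BSMT1, were the terpene synthase genes TPS03 (AT4G16740; 22 and 679 reads, 5.07, interval 4.46 to 5.75) and TPS02 (AT4G16730; 4.51), CHAT (AT3G03480; 10 and 293 reads, 4.99, interval 4.09 to 6.07), which makes a green leaf volatile, AT5G28700 (4 and 112 reads, 4.93), KCS2 (AT1G04220; 4.62), a fatty acid elongation gene, and the lipid transfer gene LTP3 (AT5G59320; 4.61). Ratios over so few reads in 1 library depend on how low values are treated. A pseudocount of 0.1 RPKM gives 4.43 for TPS03, 3.63 for TPS02, 3.69 for KCS2, 3.82 for AT5G28700 and 4.29 for CHAT. Among the lower genes it gives -4.28 for AT5G57760, -4.05 for AT4G28460 and -3.95 for AT4G39610. The most abundant lower genes were the glutathione transferase genes GSTF2 (AT4G02520; 2252 and 1042 RPKM, -1.11) and GSTF7 (AT1G02920; 936.9 and 450.4 RPKM, -1.06) with PR1 between them, and the most abundant higher genes were LOX2, the cold-regulated gene KIN2 (AT5G15970; 690.1 and 1621 RPKM, 1.23) and AOC1. Reads were absent from wild type at 81 loci and from WRKY75 RNAi at 78. The highest values among these rested on few reads, with AT4G19829 at 10 and AT3G44006 at 11 reads in WRKY75 RNAi, and ATCG00260 and AT4G25707 at 8 reads each in wild type.

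Growth-related SAUR genes, which are small auxin-induced genes, numbered 12 higher and 4 lower, but mostly on few reads, as for AT5G18030 (6 and 83 reads). Their median was 2.15, or 2.11 with loci at 0 reads set to the floor (100 percentile). Many have neighbouring locus numbers, as AT1G29430 to AT1G29510 and AT5G18010 to AT5G18080 among the higher and AT4G34770 to AT4G34810 among the lower. Their sequences were not compared, so reads shared among them are not excluded and they may not count as separate members. UDP-glycosyltransferases numbered 17 higher and 6 lower (90.7 percentile). Cytochromes P450 were even, with 18 lower and 20 higher, as were expansins and xyloglucan endotransglucosylases with 4 and 4. NAC transcription factors numbered 5 lower and 2 higher (14.6 percentile), glutathione S-transferases 8 and 4 (19.7), ethylene-response factors 8 and 7 (17.5), and MATE and ABC transporters 6 and 8 (62.1). The words for ethylene-response factors also took in DREB26 and tny but left out CBF1 and CBF2, so that count describes a word pattern. The word pattern for defensins and thionins gave 11 lower and 7 higher (20.8 percentile) but also took in enzymes named for methionine, and without these it left 3 lower and 1 higher. Of the 22 photosynthesis genes, 15 clock genes, 9 flower and meristem markers, 7 seed markers, 7 root markers and 7 guard cell and phloem markers, 0 were listed.

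A test on the reads of these 2 libraries compares the libraries, not the genotypes, and the genes counted above were chosen by the authors' thresholds. Annotated genes overlap THI2.1, BSMT1, ICS2, SARD1, UGT74F2, WRKY33, WRKY53, FRK1, FLS2, GSTF2, TCH3, ERF105, FLC, KCS2, COR15B, RAB18, HSP17.4, JAZ10, AT5G57760 and AT2G30615 on the opposite strand and SAG21 on its own strand, and since no strand setting is given their reads cannot be told apart.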

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

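Recomputed p-values, halved reads and assumed spreads were chosen after seeing the data, and the other settings before. WRKY75 had a log2 ratio of -1.71 under a pseudocount of 0.1 and -1.30 under 5 RPKM, neither of which can reverse its sign, and halving the reads widened its interval to -1.93 to -1.51. The 931 lower and 1231 higher loci became 278 and 405 at an absolute log2 ratio of at least 2, of which 200 and 324 had reads in both libraries. They stayed within 1.5 times of the deposited counts at a deposited false discovery rate of at most 0.001 (694 and 902), with values at or above 0.588 RPKM (721 and 898), with each row counted (998 and 1360), with recomputed p-values of at most 0.001 (755 and 1004) and with halved reads and p-values of at most 0.01 recomputed from them (689 and 901). The 902, and list counts of higher genes at that rate, rest on deposited p-values that often differed from those of the reads. The 694, and list counts of lower genes at that rate, rest on ranks among all tested models, which can carry the same fault. Under an assumed coefficient of variation of 0.2 between plants, 621 and 756 loci had a p of at most 0.01, and under 0.4 only 109 and 157. A spread between plants was not measured, so none of these counts is a count of genotype effects. Of 2159 loci, 1832 stayed past a log2 ratio of 1 under a pseudocount of 0.1 and 380 under 5 RPKM, a pseudocount that is large against most listed values and that cannot reverse a direction. Of 56 other named genes with reads in both libraries, 4 left their interval under 0.1 and 48 under 5 RPKM, and 2 and 25 came within 2-fold. At an absolute log2 ratio of at least 2, the lists kept as lower and higher 0 and 0 for senescence, 0 and 2 for salicylic acid synthesis, 1 and 0 for salicylic acid response, 2 and 0 for immunity, 1 and 4 for jasmonate, 0 and 1 for cold and abscisic acid, 0 and 1 for heat shock, and 0 and 0 for touch, so most list counts rest on differences of 2-fold to 4-fold. At that threshold the families kept 3 and 1 (WRKY), 0 and 2 (NAC), 1 and 0 (cysteine-rich kinases), 4 and 0 (resistance proteins), 0 and 1 (glutathione transferases), 4 and 6 (P450), 2 and 5 (glycosyltransferases), 6 and 0 (peroxidases), 0 and 3 (heat shock), 4 and 3 (defensin pattern), 1 and 2 (expansins), 1 and 4 (ethylene-response factors), 3 and 10 (SAUR), 6 and 4 (lectins) and 0 and 3 (transporters). List counts under the stricter false discovery rate and the filter on low values stayed within 1.5 times. With unmatched random lists the percentiles were 4.77 for senescence, 6.645 for salicylic acid synthesis, 13.7 for salicylic acid response, 50.5 for jasmonate, 61.1 for cold and abscisic acid and 95.7 for heat shock; the cause was not tested. The planned use of the other sheet of the lower genes was not run, as it holds ontology terms. No paired analysis was possible because each genotype has 1 library, and both carry the replicate number 1.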

Other observations

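The gene groups of the first 2 paragraphs and the tests of explanations further down were chosen after the values were seen, whereas the salicylic acid, jasmonate, touch and clock lists were fixed beforehand. The branches of indole glucosinolate methoxylation were listed in opposite directions. Of 5 genes for methoxylation at the 4 position, 4 were lower, with IGMT4 at 154.6 RPKM in wild type and 35.9 RPKM in WRKY75 RNAi (log2 ratio -2.11, interval -2.17 to -2.04), IGMT2 at -2.41, IGMT3 at -3.40 and CYP81F2 at -2.76. Both genes for the 1 position were higher, IGMT5 on 188 and 1821 reads (3.40, interval 3.18 to 3.62) and CYP81F4 on 40 and 370 reads (3.33, interval 2.86 to 3.84). A gene on the opposite strand overlaps CYP81F4 and another IGMT5. The genes IGMT2 to IGMT4 had no alignment of at least 50 bases with other transcripts that reached 97% identity over its whole length. Shorter stretches of high identity within less similar copies were not searched for, so reads shared among these genes are not excluded.

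Genes of endoplasmic reticulum bodies, stores of beta-glucosidase linked to herbivore defence, and of jacalin and myrosinase-binding lectins were listed as higher in 11 of 13 cases, with 1 lower (JAL22, on 30 and 5 reads). The regulator gene NAI1 had a log2 ratio of 2.23 (interval 2.09 to 2.38), the glucosidase gene BGLU18 of 2.42 (84.8 and 453.7 RPKM), TSA1 of 2.57 and MBP1 of 2.60 (76.0 and 461.9 RPKM). Of 24 genes of cuticular wax and cutin, 15 were higher and 0 lower, some with an overlapping gene on the other strand, among them FAR1 (3.41, on 102 and 995 reads), LACS2 (3.19), LTP1 (2.301, 50.04 and 246.6 RPKM), CER3 (1.68), CER2 (1.44) and CER6 (1.28). All 7 genes chosen for leaf volatiles were higher, including HPL1 (2.46) and TPS04 (1.05) beside TPS03, TPS02, CHAT, BSMT1 and LOX2. These groups were assembled from genes seen in the tables, so their counts are not independent evidence of direction.

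Deposited p-values of higher genes often differed from those of their own reads. Beyond 0.5% they lay above in 623 of 1360 rows, by over 10 times in 406, and below in 209, of which 186 held a p-value of 0 in the authors' deposited table although the recomputed one was as large as 1.42e-13. Among 998 rows of lower genes, 0 differed by more than 0.5%. THI2.1, with 10 and 460 reads, has a p-value of 2.41e-06 in the authors' deposited table and 2.31e-130 when recomputed. A misplacement of p-values among rows is argued against, as 38.6% of the rows of higher genes held the p of their own reads within 0.5% (rows with a deposited 0 and a recomputed p above 0 are not counted). A fault in how the upper tail was computed is a candidate explanation, since in 100% of 293 rows with 1 to 12 wild-type reads the excess was the amount typical of those wild-type reads within 5%, for example 0.000124 at 2 reads and 2.41e-06 at 10. An earlier form of this test, which asked for 1 shared p-value rather than 1 shared excess, held for 77.1% of 105 rows and missed the 90% set for it.

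Low read counts were mostly even. Among counts of 1 to 50 reads, 79.1% were even in wild type (exact 95% interval 76.4 to 81.6) and 74.6% in WRKY75 RNAi (71.6 to 77.5), against 52.2% and 51.8% above 1000 reads. Counting of the same reads for several models of a locus is argued against, as 80.0% and 75.3% were even at loci with 1 annotated transcript. Separate counting of both mates of a fragment may explain the 74.6%, in which case the intervals are too narrow, but exact duplication of reads would look alike and was not tested. No biological explanation was tested for this pattern or for that of the p-values.

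The 11 listed genes of salicylic acid response were lower, while 8 of the 10 listed jasmonate and ethylene genes were higher. Touch or wounding of the wild-type leaves shortly before freezing could have raised early response genes there. The 6 listed genes of that list had a median log2 ratio of -1.38, but that value was known before the test, CYP94B3 was higher (1.69), and the other 8 of 14 members are not listed, so this explanation cannot be told apart from genotype. Nor can harvest at another time of day. There 0 of 15 clock genes were listed, so none passed the authors' selection, but the values of unlisted genes were not used here. The test of harvest time could therefore only have pointed towards this explanation, not against it. Reduced WRKY75, a difference in infection or growth stage and chance between plants stay open and untested.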
